A study of Mus musculus with 33 samples.

How the data were processed

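The series, titled as an atlas of the aging mouse colon, holds 33 single-cell RNA-seq libraries from 11 female C57BL6/J mice. Per the labels, 5 mice were young (8 to 20 weeks) and 6 were old (90 to 108 weeks), and crypts were taken from the cecum, the proximal colon and the distal colon of each. Crypts were dissociated, stained for EpCAM and with hashtag antibodies, and EpCAM-positive cells were sorted and loaded on a 10X Genomics Chromium controller with the 3' v2 or v3.1 kit. The labels do not say which mouse had which kit. The authors deposited 1 table of raw UMI counts per library, with genes as rows and cell barcodes as columns. The submitters' processing notes credit the counting to Cell Ranger on the mm10 build and give no version. The values are whole numbers of at least 0 whose totals differ between cells. Every deposited cell has at least 1001 detected genes and at least 1559 UMIs, so cells had been filtered before deposition by a rule that the labels do not state. The strand setting of the counting is not stated, so a value for a gene that overlaps another on the opposite strand is uncertain as to its source.

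Cells were kept with at least 500 UMIs, 200 detected genes and at most 30% of UMIs from mitochondrially encoded genes. This removed 0 of the 23762 cells, in which the highest mitochondrial share was 14.99%. All cells were clustered together in scanpy 1.11.5 with anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0 under Python 3.11.15. Counts were scaled to 10000 per cell and log-transformed. Then 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering (leidenalg 0.10.2, igraph 0.11.9) at resolution 1.5 gave 43 clusters, without use of age or compartment. Clusters were not aligned between mice. A cluster was named after a cell type when its score for the markers of that type was at least 0.05 with at least 3 markers raised at least 1.5-fold, and the names end in "-like" because they rest on markers alone. A cluster also stayed unnamed where more of its 10 leading genes were markers of another type than of its own, as in cluster 35. Cluster 37, led by markers of non-epithelial cells, was divided, and a part of it was named only where at least 3 of its 10 leading genes were markers of 1 type. These limits were set after the data had been seen. Doublets were not removed. Scrublet, with an expected rate of 6%, served as an alternative, run in each of the depth batches set out below. In the high-depth batch its own threshold, set with scikit-image 0.26.0, marked 1.27% of cells. In the low-depth batch that threshold marked 0%, and 1214 cells (6.03%) were marked instead, near the expected rate.

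The mouse was the replicate throughout, and cells were never counted as replicates. The 11 mice were ranked by median UMIs per cell and split at the widest gap, by a rule fixed in advance, which gave a high-depth batch (Young 1 to 3 and Old 1 to 3) and a low-depth batch (Young 4 and 5, Old 4 to 6). This gap was 1.48 on the log2 scale and the next widest 0.766. Low-depth libraries of different mice shared 222 barcodes, against 213.6 expected for random draws from the 737280 barcodes of the v2 list. High-depth libraries shared 3 with low-depth ones (99.1 expected) and 1 with other high-depth mice (7.0 expected). These counts argue against 1 barcode list for both batches, and the low-depth count is near that for v2. The labels do not name the kit of a mouse. For age, UMIs of a class were summed per mouse where it had at least 20 cells of the class, and old was compared with young by the two-sided quasi-likelihood F test of edgeR 4.0.16 (limma 3.58.1, with version 1.17.8 of data.table, R 4.3.3) with the depth batch as a term. An offset carried the library size and each gene's effect of the mix of compartments. For compartments, UMIs were summed per library and class and the mouse was a block, so that only mice with at least 2 compartments inform the test. Low-depth libraries of the same mouse shared 0 barcodes, against 37.4 expected for random draws from the v2 list. The compartments of a mouse may thus have been captured together and parted by hashtag. Whether RNA passed between them was not tested. The interaction of age with compartment was an F test with 2 degrees of freedom within that block. Genes were filtered with filterByExpr, scaled by TMM, fitted with a prior count of 2, and called at a Benjamini-Hochberg adjusted p below 0.05. The same pipeline was tested on simulated data with a between-mouse coefficient of variation of 0.25. There it called 73% of the genes changed by 1 on the log2 scale between ages in the colonocyte-like class and 51% in the stem-like class, with 2.26% and 3.2% false calls. For compartments the false calls were 6.4% in the colonocyte-like class, above the 5% aimed at, 0.995% in the goblet-like and 1.92% in the stem-like class. All these rates were taken over simulated genes above a minimum total count. They do not cover genes with fewer counts.

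Shares of the epithelial classes are percentages of the cells not named as immune, and the share of T cell-like cells is of all cells. The 29 libraries with at least 50 cells entered, and 4 with fewer did not. For age, each mouse gave 1 value, its mean deviation from the mean of the compartment, compared by a two-sided exact permutation test over 462 regroupings of the mice. For compartments, differences within mice were tested by a two-sided exact sign-flip permutation test. Adjusted p values cover 7 age tests, 21 compartment tests, and 7 tests in each compartment for age within compartments. A total of 32 gene lists, 20 of pathways and 12 of cell type markers, were fixed before the data were examined, as were the comparisons and most alternatives. They were tested with limma's camera at a preset inter-gene correlation of 0.01, with an estimated correlation and limma's fry as alternatives, where at least 5 members were measured. The marker list of a class is not read as a result within that class, since it named the cells.

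Named genes follow a rule fixed in advance: in each comparison the 8 largest rises and 8 largest falls among called genes with a standard symbol and a mean log2 CPM of at least 5, then up to 4 members of each list with the smallest p. S100g, 0610040F04Rik, Meg3, Kcnq1ot1, Kif26a, Bex4, Ptpn6 in the colonocyte-like class, and Scnn1a fall outside it and were chosen after their values were seen. Some genes and 1 list that the rule covers are not reported here. Positions are from GENCODE vM21 on GRCm38, the mm10 build.

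The sample names give young and old mice the same numbers from 1 to 5, but the labels do not say that a number links them. It was checked whether same-numbered mice deviate together from their age group's mean: correlations over genes were 0.54 to 0.82 in all 18 pairs of class and number, but -0.03 to 0.53 within the depth batches, with 14 of 18 over 0.1, so the numbers pair the samples in part through the batch. A block on the number was therefore an alternative and not the main model. Other alternatives were no batch term, each batch or compartment alone, DESeq2 1.42.0, limma-voom, other gene filters and cell minimums, no compartment offset, at most 200 cells per library and class, other clustering resolutions (0.8 and 2.5), removal of doublets, naming the unnamed clusters, and leaving out each mouse in turn. Enteroendocrine-like and tuft-like cells were not tested for age in expression, since only 2 young mice had 20 such cells. Figures were drawn with matplotlib 3.10.9.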

Results

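The 33 libraries hold 23762 cells of EpCAM-sorted crypts from 11 mice, 5 young and 6 old, with 1 library per mouse from the cecum, the proximal colon and the distal colon. Libraries ranged from 18 cells (Young 2, proximal colon) to 3403 cells (Young 5, cecum), and from 536778 to 21288806 UMIs. The mice fell into 2 depth batches. The 6 high-depth mice (Young 1 to 3, Old 1 to 3) had medians of 28055.5 to 36341 UMIs per cell but gave only 3627 cells. The 5 low-depth mice (Young 4 and 5, Old 4 to 6) had 3982 to 10039 UMIs per cell and gave 20135 cells. Young 5 stood apart: it had the lowest median, 3982 UMIs, the most cells, 6070, and library medians of 1.65% to 2.2% of UMIs from mitochondrially encoded genes, against 4.64% to 10.3% in the other mice.

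By their markers, 6883 cells were colonocyte-like (absorptive cells, with Slc26a3 and Car1 among the markers), 5490 goblet-like (Muc2, Tff3), 4251 stem-like (Lgr5, Ascl2) and 3642 cycling-like (Mki67, Top2a). A further 539 cells were tuft-like, 326 enteroendocrine-like and 29 T cell-like, of which 21 came from Young 5, and the rest stayed in unnamed clusters. Clusters often separated mice rather than cell types, so that a class pools clusters from different mice. In the colonocyte-like class, cluster 0 held 43.6% of the young cells and 99.3% of its cells came from Young 5, while clusters 25 and 8 held 15.8% and 15.6% of the old cells. The young stem-like cells lay mostly in cluster 2 (51.3%) and the old ones in clusters 1 and 7 (35.9% and 27.3%). Of the goblet-like cells, the largest parts lay in clusters 19 and 9 in young mice and 6 and 3 in old mice, and of the cycling-like cells in cluster 14 in young and 5 in old mice.

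The first question was whether the composition of the crypts differed with age, given that the sort keeps EpCAM-positive cells alone and that the depth gap runs across both ages. Goblet-like cells made up 21.5% of the cells of young and 27.9% of those of old mice, and colonocyte-like cells 29.3% and 22.7%. With compartments balanced, old mice differed from young ones by 7.2 ± 4.87 percentage points (SE, 5 and 6 mice) in goblet-like cells. The difference was -5.8 ± 6.32 points in colonocyte-like cells and 3.09 ± 1.98 points in stem-like cells. None passed the two-sided exact permutation test (p = 0.169, p = 0.383 and p = 0.169, adjusted p = 0.591, 0.837 and 0.591). The exact permutation test was not passed either by cycling-like (-0.953 points, p = 0.742), tuft-like (0.855, p = 0.478), enteroendocrine-like (0.0354, p = 0.926) or T cell-like cells (0.0569, p = 0.875). Paired by number, with 5 pairs, the goblet-like share was higher in the old mouse of 5 of 5 pairs (8.25 points on average) and the colonocyte-like share lower in 5 of 5 (-7.2 points). Both gave the smallest exact sign-flip p that 5 pairs allow, 0.0625, so the paired test could not pass (adjusted p = 0.219 for each). Within the high-depth and the low-depth mice the goblet-like difference was 10.5 and 2.39 points, the colonocyte-like one -5.94 and -5.05, and the stem-like one 1.08 and 4.61. In the distal colon alone, goblet-like cells made up 27.1% in 5 young and 41.4% in 6 old mice (14.3 ± 4.77 points). Colonocyte-like cells made up 18.9% and 8.03% (-10.8 ± 5.29 points). The exact permutation p values of 0.0173 and 0.0411 became 0.121 and 0.144 after adjustment over the 7 classes, so neither passed. Unnamed clusters took 38.4% ± 8.56 (SD) of the distal cells of young and 34.6% ± 5.09 of those of old mice. They took 14.1% ± 11.4 and 6.79% ± 8.58 in the cecum, and 2.67% ± 0.947 and 2.62% ± 0.493 in the proximal colon.

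Composition was next compared between compartments of the same mice. Stem-like cells made up 33.2% of the proximal colon against 15.2% of the cecum in 7 mice (17.9 ± 4.04 points, higher in 7 of 7, exact sign-flip p = 0.0156, adjusted p = 0.041). Colonocyte-like cells were lower there (28.8% against 38.1%, lower in every one of the 7 mice, exact p = 0.0156, adjusted p = 0.041). From cecum to distal colon, colonocyte-like cells fell from 38.4% to 13.7% (-24.7 ± 4.42 points, lower in 10 of 10 mice, exact p = 0.00195, adjusted p = 0.0273). Cycling-like cells fell from 15.8% to 8.98% (-6.79 ± 1.04 points, adjusted p = 0.0273). Goblet-like cells rose from 20.7% to 34.6% (13.97 ± 5.21 points, higher in 8 of 10 mice, adjusted p = 0.041). The stem-like difference of -7.34 ± 2.82 points did not pass (adjusted p = 0.0697). From proximal to distal colon, in 8 mice, goblet-like cells rose by 22.1 ± 4.23 points. Colonocyte-like, stem-like and cycling-like cells fell by 16.7 ± 4.42, 28.9 ± 2.45 and 7.63 ± 1.21 points. Each gave the smallest exact p that 8 pairs allow, 0.00781 (adjusted p = 0.0273). Unnamed clusters held 36.3% of the distal, 10.5% of the cecal and 2.64% of the proximal cells. Colonocyte markers were among the leading genes of clusters 15 (Tgm3) and 18 (Muc3), each 97.3% distal. Part of a lower distal share may thus be cells left unnamed, which was not tested. The closest class had little support: clusters 18 (stem) and 24 (cycling) had 0 markers raised, and cluster 15 (myeloid) scored -0.006. This alternative therefore cannot tell where their cells belong. With each unnamed cluster given its closest class, the stem-like difference between distal and proximal colon shrank to -4.91 points (adjusted p = 0.434). The cycling-like differences shrank to -2.84 against the cecum and -4.03 against the proximal colon (adjusted p = 0.263 and 0.213), the stem-like rise from cecum to proximal colon to 11.6 (0.0923), and none of the 9 calls passed. At clustering resolution 0.8 that stem-like rise was 9.51 points (adjusted p = 0.146). Leaving out any 1 of Young 3, Young 5, Old 2, Old 4, Old 5 and Old 6 ended every one of these distal calls, with adjusted p up to 0.0547 for all but the goblet-like call against the cecum. That call also ended without Young 2 (adjusted p up to 0.082), and the proximal calls ended without any 1 of their 7 mice (Young 3 to 5, Old 2, Old 4, Old 5 and Old 6; up to 0.082). The differences kept their sign, and 1 pair fewer raises the smallest p that can be reached.

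**Figure D1:**
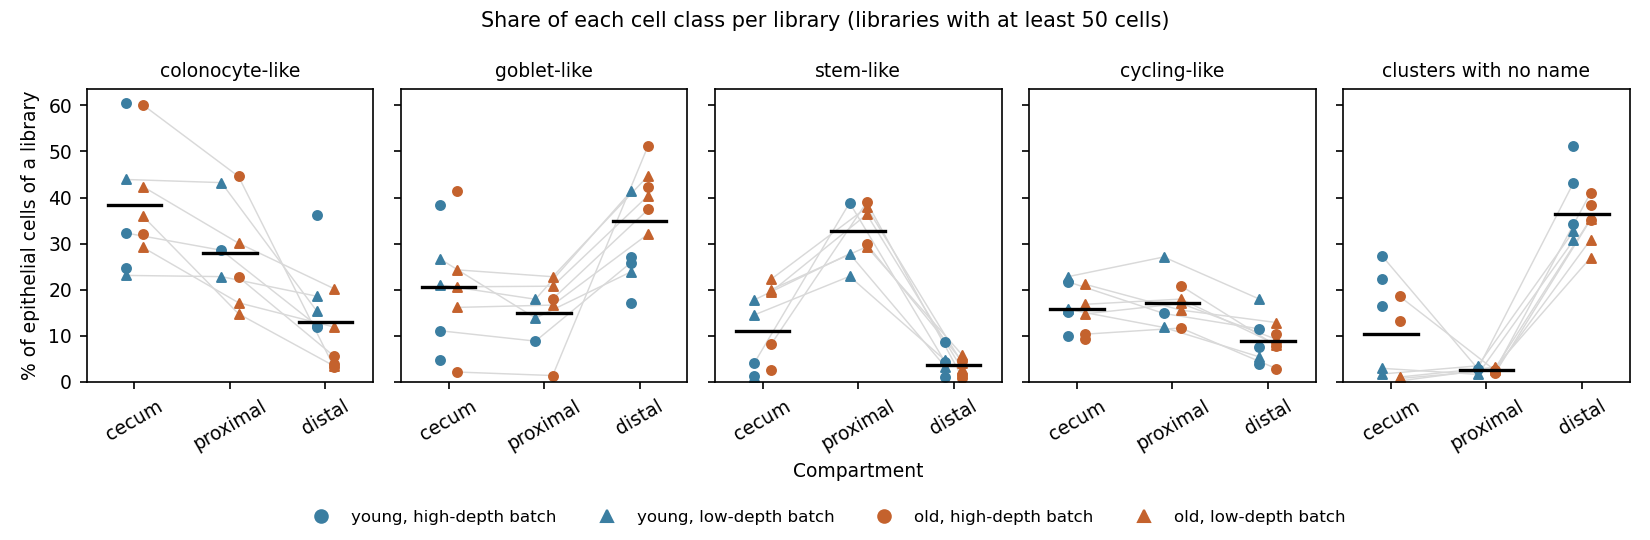
Share of each class in % of the epithelial cells of a library (vertical axis) by compartment (horizontal axis). There is 1 point per library of at least 50 cells, with grey lines joining the libraries of a mouse and black lines at the means. Colonocyte-like cells average 38.4% in the cecum and 13.7% in the distal colon in the 10 mice with both, and the unnamed clusters average 36.3% in the distal colon.

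Few genes were called for age in any class, and in the simulated data the test missed part of the genes changed by 1 on the log2 scale. The same mice gave each class, so a gene called in several classes is not independent evidence. S100g, which encodes the intestinal calcium-binding protein calbindin-D9k, fell in all 4 classes tested. Its level in the colonocyte-like class fell from 139 to 19.2 CPM (log2 change -2.98 ± 0.25, SE, 5 young and 6 old mice, edgeR adjusted p = 2.81e-05). It fell by 2.27 ± 0.34 on the log2 scale in the goblet-like, by 2.62 ± 0.37 in the stem-like (4 and 5 mice) and by 2.39 ± 0.33 in the cycling-like class (adjusted p = 0.00825, 0.00886 and 0.00364). Cox6b2, the testis isoform of a cytochrome c oxidase subunit, fell from 33.2 to 11.3 CPM in the stem-like class (-1.67 ± 0.18, adjusted p = 0.000968) and from 8.35 to 2.79 CPM in the colonocyte-like class (-1.71 ± 0.24, adjusted p = 0.00427). It was also called in the goblet-like (-1.70 ± 0.27, adjusted p = 0.0163) and cycling-like classes (-1.36 ± 0.22, adjusted p = 0.0174). The antisense transcript 0610040F04Rik, which overlaps Bhlhe40, rose in the colonocyte-like (2.83 ± 0.36, 1.04 to 8.33 CPM, adjusted p = 0.00427), stem-like (2.23 ± 0.27, adjusted p = 0.00202) and cycling-like classes (2.47 ± 0.34, adjusted p = 0.00364). S100g (ENSMUSG00000040808) lies on chromosome X (162961992 to 162964599, overlapping Ctps2 on the other strand). Cox6b2 lies on chromosome 7 (4751792 to 4753094) and 0610040F04Rik on chromosome 6 (108577039 to 108660934). In the colonocyte-like class S100g changed by -2.83 among the high-depth (adjusted p = 0.00302) and -3.21 among the low-depth mice (adjusted p = 0.0202). In the stem-like class, with 2 young and 2 old mice at high depth, the values were -1.60 and -3.11 (adjusted p = 0.685 and 0.00915), and in the cycling-like class -1.32 and -3.01 (1.00 and 0.00226). In the goblet-like class S100g changed by -2.62 at low depth (adjusted p = 0.00308) and had too few counts at high depth. Among colonocyte-like cells every old mouse lay below every young one of its batch. Cox6b2 changed there by -1.26 and -2.14 (adjusted p = 0.378 and 0.0877) and 0610040F04Rik by 2.46 and 3.27 (0.452 and 0.0342). Leaving out 1 mouse ended the Cox6b2 call in the goblet-like class for Young 4, Young 5, Old 4, Old 5 and Old 6 (adjusted p up to 0.0826). In the cycling-like class it ended for every mouse but Young 2 and Old 3 (up to 0.092). With a block pairing mice by number the adjusted p of Cox6b2 was 0.0559 in the colonocyte-like and 0.0593 in the goblet-like class. A total of 35 genes were called in at least 1 class, 25 of them in 1, 7 in 2, 1 in 3 and 2 in all 4.

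**Figure D2:**
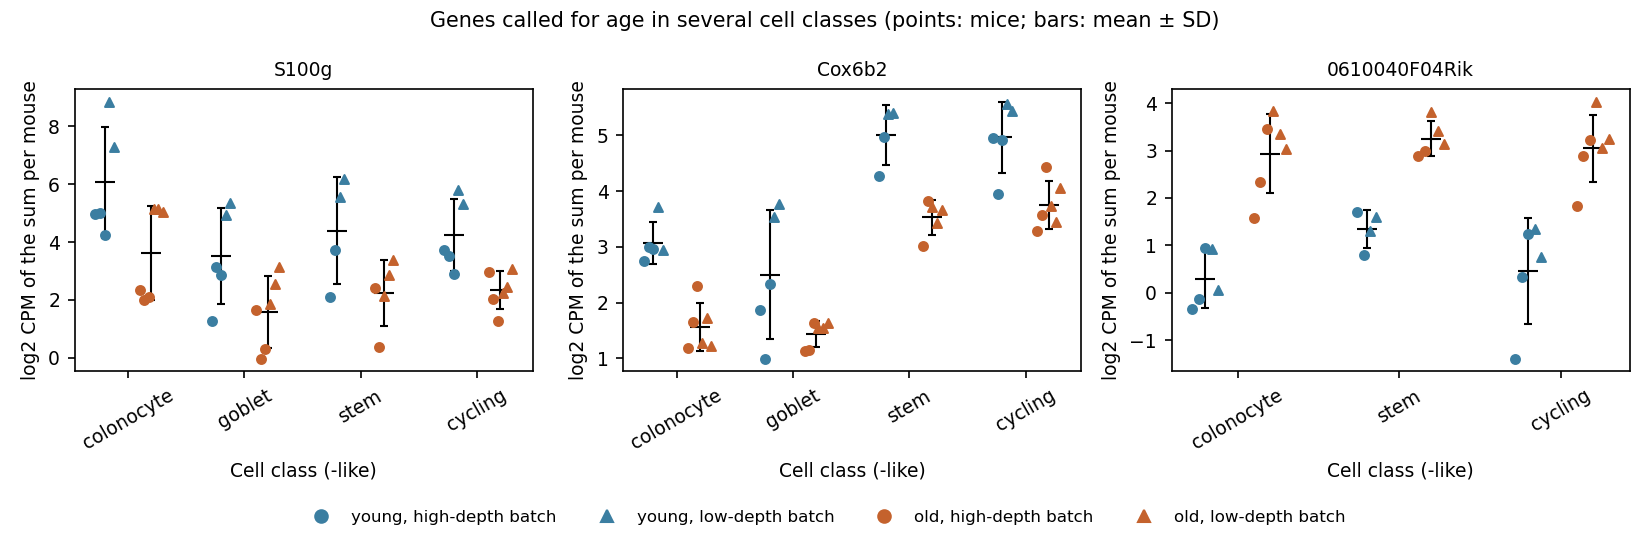
Level of S100g, Cox6b2 and 0610040F04Rik as log2 CPM of the sum per mouse (vertical axes) in the cell classes in which each was called (horizontal axes). There is 1 point per mouse, with colour for age, shape for depth batch, and bars at the mean ± SD of each age. In the colonocyte-like class every old mouse is below every young mouse of its batch for S100g. The lowest young and highest old values are 18.7 and 4.79 CPM at high depth and 154 and 35.2 CPM at low depth.

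Of 10733 genes in the colonocyte-like class 17 were called, 10 higher and 7 lower in old mice. Reg3g, an antimicrobial lectin, fell from 122 to 40.3 CPM (-1.66 ± 0.26, adjusted p = 0.0129; high-depth -2.15, low-depth -1.37), the 1 called member among 17 measured genes of mucosal defence. Its relative Reg3b had 227 CPM in young and 61.2 CPM in old mice and did not pass (-1.99 ± 0.55, adjusted p = 0.331, and 0.00773 with the block on mouse number). Ly6e, an interferon-inducible surface protein, rose from 79.3 to 127 CPM (0.70 ± 0.11, adjusted p = 0.0129; high-depth 0.71, low-depth 0.72). So did Itih5 (0.69 ± 0.13, adjusted p = 0.0341; 0.63 and 0.78), of the inter-alpha-trypsin inhibitor heavy chains, and Ptpn6 (0.71, adjusted p = 0.0266; 0.74 and 0.69), which encodes a tyrosine phosphatase. The Ly6e call ended without Young 2, Young 3 or Young 4 (adjusted p up to 0.0745). That of Reg3g ended without Young 3, Young 4 or Old 2 (up to 0.0796). Itih5 was lost without any of Young 2 to 5, Old 2, Old 3, Old 5 and Old 6 (up to 0.142) and with the block (0.177). Ptpn6 was lost without any of Young 1 to 4, Old 2, Old 3, Old 4 and Old 6 (up to 0.125) and with the block (0.163). The count itself fell to 6 without Young 3, 8 without Young 2 or Old 2, 9 without Young 4 and 11 without Old 6. It was 10 with the block, and was 2 among the high-depth and 3 among the low-depth mice alone.

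In the goblet-like class 15 of 10688 genes were called, 9 higher and 6 lower in old mice. Meg3, a maternally expressed imprinted long noncoding RNA on chromosome 12 (109541001 to 109571726), fell from 43.8 ± 55.3 (SD, 5 mice) to 0.401 ± 0.876 CPM (6 mice; log2 change -5.88 ± 0.82, adjusted p = 0.00692; high-depth -4.30, low-depth -9.72). Of it 3 old mice had no UMI, so the fitted size depends on the prior count. Kif26a, of the kinesin family, rose by 2.82 (adjusted p = 0.00692; 2.18 and 3.45). Vsig2, a membrane protein of the immunoglobulin superfamily, rose from 69.7 to 132 CPM (0.89 ± 0.15, adjusted p = 0.0248; 1.09 and 0.66). Sprr1a, a small proline-rich protein, rose from 1.67 to 8.62 CPM (2.00 ± 0.35, adjusted p = 0.0248; 2.07 at low depth, too few counts at high depth and with the block). The calls of Meg3 and Kif26a held with each mouse left out. That of Vsig2 ended without Young 1, Young 3, Young 4, Old 3, Old 5 or Old 6 (adjusted p up to 0.11) and that of Sprr1a without Young 4 or Young 5 (up to 0.218). The count was 32 without Young 2, 25 without Old 1, 8 without Old 5, 6 without Old 4, 5 without Young 4 and 5 without Old 6. Among the high-depth mice alone edgeR called 0 genes in this class, and among the low-depth mice 24.

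In the stem-like class 8 of 10515 genes were called (3 higher, 5 lower in 5 old against 4 young mice) and in the cycling-like class 10 of 10679 (6 higher, 4 lower). Bex4 fell in both, by 2.62 and 2.09 on the log2 scale (adjusted p = 0.000968 and 0.000311; stem-like -2.05 at high and -2.92 at low depth, cycling-like -1.99 and -2.13). Its X-linked neighbour Bex1 fell by 1.40 in the stem-like class (adjusted p = 0.00656; -2.01 and -1.05). Pibf1, a centrosomal protein, rose in both, by 0.97 and 0.94 (adjusted p = 0.0114 and 0.0288; 0.91 and 0.96 in the stem-like class, 0.90 and 1.06 in the cycling-like). In the cycling-like class Ceacam10, a cell adhesion protein, rose by 1.58 (adjusted p = 0.0174; 1.11 and 2.11), Ptpn6 by 1.07 (adjusted p = 0.00894; 1.13 and 1.04) and Kif26a by 4.09 (adjusted p = 0.0154; 4.45 at low depth, not testable with the block). The Bex1 and Bex4 calls held with each mouse left out. Pibf1 was lost in the stem-like class without Young 1, Young 4 or Old 2 (adjusted p up to 0.0713). In the cycling-like class it was lost without Young 1, Young 3, Young 4, Young 5, Old 2, Old 3 or Old 6 (up to 0.123). Ceacam10 was lost without Young 1, Young 4, Young 5 or Old 2 (up to 0.123), Ptpn6 without Young 4 (0.0579) and Kif26a without Young 4 or Young 5 (up to 0.247). The stem-like count was 19 without Young 5 and 37 with the block on mouse number. The cycling-like count was 17 without Young 2, 3 without Young 4, 5 without Young 5 and 6 without Old 2, Old 5 or Old 6. High-depth and low-depth mice alone gave 8 (2 against 2 mice) and 3 genes in the stem-like and, by edgeR, 0 and 5 in the cycling-like class. For all 4 classes the calls depended on the batch term: without it 0, 0, 0 and 2 genes were called in the colonocyte-like, goblet-like, stem-like and cycling-like classes.

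Camera called gene lists for age in each class, but none of the camera calls held with an estimated correlation. Genes of goblet cells were lower in the stem-like cells of old mice (21 measured, 0 called over all genes, 7 lower when adjusted over the list alone, median log2 change -0.61, adjusted p = 1.78e-10, and adjusted p = 0.229 with an estimated correlation). Tff3, the trefoil peptide, had 574 CPM in young and 258 CPM in old mice (-1.40 ± 0.28, adjusted p = 0.0871), and the mucin Muc2 a change of -1.03 (adjusted p = 0.273). With the block on mouse number these became 0.0365 and 0.0394. Genes of dissociation and heat shock were lower in the same class (22 measured, 0 called, 3 lower when adjusted over the list alone, median -0.61, adjusted p = 2.04e-09, and adjusted p = 0.229 with an estimated correlation). Atf3, of that list, changed by -1.70 (adjusted p = 0.645, 0.0107 with the block). In the colonocyte-like class this list had 0 called genes and 1 lower when adjusted over the list alone (median -0.23, adjusted p = 7.7e-05, and adjusted p = 0.558 with an estimated correlation). The heat shock gene Hspa1a changed there by -1.51 (adjusted p = 0.315). Genes of cycling cells were lower in goblet-like cells of old mice (21 measured, 0 called, 12 lower when adjusted over the list alone, median -0.67, adjusted p = 2.69e-07, and adjusted p = 0.688 with an estimated correlation). Ccnb1, a mitotic cyclin, changed by -1.10 (adjusted p = 0.0828) and Ube2c by -1.32 (adjusted p = 0.201, 0.00535 with the block).

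Cytosolic ribosomal protein genes had medians of -0.26 in the colonocyte-like, -0.14 in the goblet-like, -0.21 in the stem-like and -0.09 in the cycling-like class (82 measured, 0 called in each). The list gave adjusted p = 3.21e-19, 8.46e-07, 1.78e-10 and 0.000224, and with an estimated correlation adjusted p = 0.558, 0.688, 0.517 and 0.732. The nuclear-encoded genes of oxidative phosphorylation had medians of -0.08 in the colonocyte-like and -0.14 in the goblet-like class (76 measured, Cox6b2 the 1 called in each). Their adjusted p was 0.000669 and 4.98e-14, and with an estimated correlation adjusted p = 0.82 and 0.688. The 13 mitochondrially encoded genes had medians of 0.35, 0.50 and 0.35 in the colonocyte-like, stem-like and cycling-like classes, with 0 called. Camera gave adjusted p = 0.00017, 4.11e-06 and 0.000142, and with an estimated correlation adjusted p = 0.628, 0.338 and 0.567. Of these, mt-Co1 changed by 0.42 and 0.50 in the colonocyte-like and stem-like classes (adjusted p = 0.691 and 0.893). Without Young 5, whose libraries had the lowest mitochondrial shares, their adjusted p was 0.149, 0.0225 and 0.565. In the cycling-like class genes of cholesterol synthesis were lower (22 measured, 0 called, median -0.16, adjusted p = 4.87e-06, and adjusted p = 0.295 with an estimated correlation). Interferon-stimulated genes were lower too (16 measured, 0 called, 2 lower when adjusted over the list alone, median -0.27, adjusted p = 0.000441, and adjusted p = 0.245 with an estimated correlation). Of 24 lists tested, camera called 8, 8, 11 and 9 in the 4 classes, an estimated correlation 0 in each, and fry 0, 0, 1 and 0. The counts moved to 5 without Young 1 in the colonocyte-like class. They moved to 3 without Old 3, 5 without Old 4 and 13 without Old 2 in the goblet-like class and to 5 without Young 5 in the cycling-like class.

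The next question was how the same class differs along the bowel. Of the 9483 genes tested in colonocyte-like cells, 4184 were called between distal colon and cecum (1978 higher, 2206 lower in the distal colon; 7 and 9 libraries). There were 2551 called between proximal colon and cecum (1311 and 1240; 7 and 9) and 2078 between distal and proximal colon (976 and 1102; 7 each). Aqp4, a water channel (chromosome 18, 15389496 to 15410982), had 10.2 ± 6.48 CPM (SD, 9 libraries of at least 20 cells) in the cecum, 291 ± 231 in the proximal (8) and 1012 ± 242 in the distal colon (7). Its log2 change was 6.98 ± 0.29 from cecum to distal colon (SE, adjusted p = 3.67e-14) and 4.46 ± 0.29 to the proximal colon (adjusted p = 1.49e-10). Anxa1, a phospholipid-binding protein, rose by 5.10 ± 0.14 from cecum to distal colon. Ggh, a folate hydrolase, rose by 5.14 ± 0.23 and Scnn1a, a subunit of the epithelial sodium channel, by 2.39 ± 0.22 (2.24 ± 0.25 against the proximal colon). Ces1g, a carboxylesterase, fell by 4.51 ± 0.20 and Slc51a, a subunit of the basolateral bile acid exporter, by 3.59 ± 0.35. The proximal colon had more Reg3b (3.79 ± 0.46), Reg3g (2.56 ± 0.37) and Slc40a1, the iron exporter ferroportin (3.04 ± 0.17), than the cecum (adjusted p = 1.76e-06, 1.56e-05 and 1.73e-11). From proximal to distal colon Reg3b fell by 3.48 ± 0.58 (adjusted p = 0.000131). Hoxb13, the most posterior gene of its cluster (chromosome 11, 96194316 to 96197447), rose by 6.53 ± 0.38 from cecum and by 4.13 ± 0.40 from proximal to distal colon (adjusted p = 6.87e-12 and 1.45e-07). Hoxb7 fell by 3.89 ± 0.23 from cecum to distal colon (adjusted p = 9.61e-12).

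**Figure D3:**
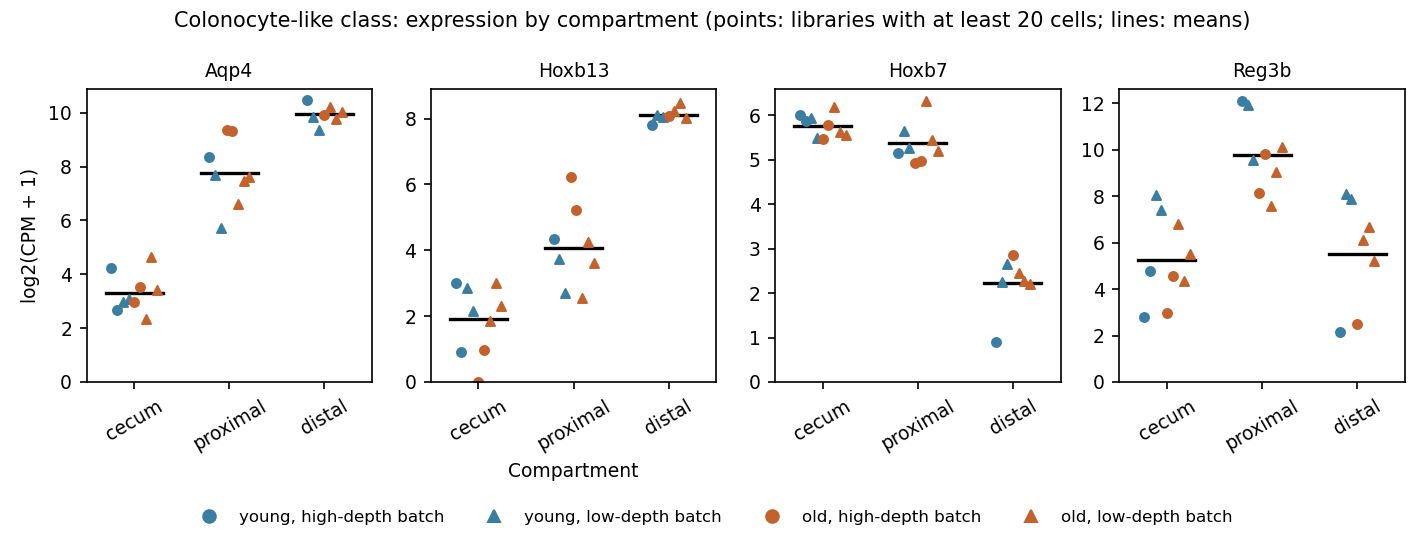
Level of Aqp4, Hoxb13, Hoxb7 and Reg3b in colonocyte-like cells as log2 of CPM plus 1 (vertical axes) by compartment (horizontal axes). There is 1 point per library of at least 20 cells, with colour for age, shape for depth batch and lines at the means. Aqp4 and Hoxb13 are highest in the distal colon (1012 and 277 CPM on average). Hoxb7 is lowest there (4.02 CPM), and Reg3b is highest in the proximal colon (1517 CPM).

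In goblet-like cells, of 9106 genes, 3305 were called between distal colon and cecum (1492 higher, 1813 lower; 9 and 8 libraries). There were 2834 called between proximal colon and cecum (1353 and 1481; 7 and 8) and 2252 between distal and proximal colon (974 and 1278; 9 and 7). Sval1 rose by 5.42 ± 0.34 from cecum to distal colon, and Best2, an anion channel of goblet cells, by 2.18 ± 0.16 and by 3.47 ± 0.20 from the proximal colon. Sct, which encodes the hormone secretin, fell by 6.10 ± 0.26 (adjusted p = 5.92e-15), from 1995 ± 723 CPM in the cecum to 28.1 ± 24.8 CPM in the distal colon. The carbonic anhydrase-related Car8 fell by 3.88 ± 0.19, and fell by 4.45 ± 0.20 from the proximal colon. Plet1 was highest in the proximal colon, at 1213 ± 451 CPM, with a rise of 4.49 ± 0.45 from the cecum and a fall to the distal colon of -3.27 ± 0.37. Ffar2, a receptor for short-chain fatty acids, and Cd177 rose by 2.14 ± 0.16 and 2.52 ± 0.24 from cecum to proximal colon. Aqp1, a water channel, fell by 2.57 ± 0.16 from proximal to distal colon. Cyp51, an enzyme of cholesterol synthesis, rose from cecum to distal colon by 1.16 ± 0.12 (adjusted p = 6.34e-08). Hoxb13 rose by 4.97 ± 0.24 and 4.20 ± 0.24 against cecum and proximal colon, and Hoxb7 fell by 4.91 ± 0.21 against the cecum.

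In stem-like cells, of 10251 genes, 1549 were called between proximal colon and cecum (764 higher, 785 lower; 6 libraries each). There were 1009 called between distal colon and cecum (437 and 572; 3 and 6) and 392 between distal and proximal colon (160 and 232; 3 and 6). Adh1, an alcohol dehydrogenase, rose by 3.26 ± 0.15 from cecum to distal colon (adjusted p = 5.47e-12) and Hoxb13 by 6.14 ± 0.45. Hoxb7 fell by 3.43 ± 0.41 and the carbonic anhydrase Car4 by 3.74 ± 0.36. In the proximal colon Edn1, the precursor of endothelin-1, was higher than in the cecum by 1.98 ± 0.17, the calcium-binding S100a6 by 1.57 ± 0.10 and Reg3b by 1.58 ± 0.23. Car4 and Cps1, an enzyme of the urea cycle, fell by 2.32 ± 0.15 and 1.44 ± 0.21. Hoxb6, Hoxb7 and Hoxb8 fell from proximal to distal colon by 3.97 ± 0.59, 3.51 ± 0.41 and 2.56 ± 0.48 (adjusted p = 0.000159, 6.73e-06 and 0.0023). The last call was lost without Old 4 (-2.27, adjusted p = 0.0538). Only 3 distal libraries had 20 stem-like cells. With the unnamed clusters given their closest class the distal counts rose to 5168 and 4306 and the proximal one to 2661. That naming counts cluster 18, with 0 stem markers raised, as stem-like, so these distal counts cannot be read as those of stem-like cells. Against the cecum the distal count was 579 without Old 4 and 439 without Old 6. The proximal one was 945 without Young 4, 949 without Old 4 and 808 without Old 6. Between distal and proximal colon it was 233 without Old 4 and 158 without Old 6, and in colonocyte-like cells 1296 without Young 4.

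In the compartments, the cells compared came largely from different clusters. Of the colonocyte-like cells, cluster 0 held 34.4% in the cecum, cluster 12 held 28.9% in the proximal and cluster 13 held 57.2% in the distal colon. Of the goblet-like cells, cluster 11 held 32.8%, cluster 3 held 63.4% and cluster 10 held 33.9%. For stem-like cells these were cluster 1 (66.5%), cluster 4 (32.5%) and cluster 7 (40.0%). Several genes named above for the distal colon, such as Aqp4, Ggh, Adh1 and Hoxb13, also led the unnamed distal clusters. Without the mouse as a block the proximal counts against the cecum were 1487, 1811 and 479 in colonocyte-like, goblet-like and stem-like cells. The distal counts were 1341 and 141 against the proximal colon in goblet-like and stem-like cells, and 508 against the cecum in stem-like cells.

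With an estimated correlation, 1 of the 9 lists that camera called in colonocyte-like cells between distal and proximal colon held, and 0 in the other compartment comparisons. Genes of cholesterol synthesis rose from cecum to distal colon in 13 of 22 cases in colonocyte-like and 18 of 22 in goblet-like cells, the counts over the list alone being 13 and 18. Camera gave adjusted p = 0.00358 and 8.2e-08, and with an estimated correlation adjusted p = 0.526 and 0.152. Genes of cycling cells fell in goblet-like cells, all 20 of them from cecum to distal colon and all 20 to the proximal colon (adjusted p = 1.34e-13 and 8.14e-10, and with an estimated correlation adjusted p = 0.11 and 0.13). Of the nuclear-encoded genes of oxidative phosphorylation, 62 of 75 fell in goblet-like and 50 of 76 in stem-like cells from cecum to distal colon, with 1 rising in each (64 and 60 lower over the list alone). Their adjusted p was 9.23e-19 and 4.12e-18, and with an estimated correlation adjusted p = 0.141 and 0.312. Hox genes moved in both directions. From cecum to distal colon 4 of 16 rose and 8 fell in goblet-like cells and 2 of 15 rose and 7 fell in stem-like cells (9 and 8 lower over the list alone). Camera gave adjusted p = 0.011 and 0.0284, and with an estimated correlation adjusted p = 0.11 and 0.221. Of the genes of mucosal defence, 7 of 17 rose and 2 fell from cecum to proximal colon in colonocyte-like cells (adjusted p = 0.000694, and with an estimated correlation adjusted p = 0.54). Of 20 genes of ER chaperones 12 rose from cecum to proximal colon in goblet-like cells (adjusted p = 1.08e-07, and with an estimated correlation adjusted p = 0.13).

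Whether the age difference itself differed between compartments was tested in colonocyte-like and goblet-like cells. In goblet-like cells it did for 4 of 9106 genes (420 at an unadjusted p below 0.05; 3 by the DESeq2 likelihood ratio test). The 4 were named after their values were seen. For Ccz1, a vesicle trafficking protein, the old minus young difference in the distal colon less that in the cecum was -1.07 on the log2 scale (proximal less cecum 0.07, adjusted p = 0.00119). The others were Spink1, a secreted protease inhibitor (3.78 distal and 3.22 proximal, adjusted p = 0.0136), the imprinted antisense RNA Kcnq1ot1 (-5.23 and -1.49, adjusted p = 0.0223) and Ly6e (-0.86 and 0.18, adjusted p = 0.0223). Over all compartments Kcnq1ot1 fell with age in goblet-like cells (-2.73, adjusted p = 0.0449; high-depth -2.60, low-depth -3.17). That call was lost without any of Young 1, Young 3, Young 4, Young 5, Old 1, Old 4, Old 5 and Old 6 (adjusted p up to 0.264). Ccz1 held with each mouse left out. Spink1 was lost without Old 4 (adjusted p = 0.425) and Kcnq1ot1 without Young 4, Old 1, Old 3, Old 4, Old 5 or Old 6 (up to 0.366). Ly6e was lost without Young 4, Young 5, Old 1, Old 3, Old 4, Old 5 or Old 6 (up to 0.224). The count was 1 without Old 4, 2 without Old 1, Old 3 or Old 5, and 7 without Young 3. In colonocyte-like cells edgeR called 0 of 9483 genes, with 358 at an unadjusted p below 0.05, and the DESeq2 likelihood ratio test called 3. Leaving out Young 4, Young 5 and Old 2 in turn gave 2, 6 and 4.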

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

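The tests of free RNA, of the depth batches for S100g, of Young 5 alone and of ileal tissue were chosen only after the results were seen, while the regroupings of the mice and the test of the low-depth mice for the mitochondrial genes were set before.

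S100g fell with age in the 4 classes tested, and the first question is whether the fall outside the colonocyte-like class is free RNA from colonocytes. In that case S100g would reach the other classes in the same proportion as other colonocyte transcripts. In young mice its level relative to colonocyte-like cells was over 2 times the lowest such ratio of the colonocyte markers in 5 of 5 mice in the cycling-like (2.25 to 8.57 times), 4 of 4 in the stem-like (6.5 to 41.1 times) and 4 of 5 in the goblet-like class (0.921 times in Young 1), but the median marker was too in 13 of 14 mice and classes. It was over 2 times the median marker ratio in 0 of 5, 2 of 4 and 0 of 5, so free RNA cannot be told apart in these classes, since the markers themselves spread widely. A difference between depth batches is argued against in the colonocyte-like class, where every young mouse lay above every old one of its batch in 2 of 2 batches. For the other classes the criterion was another: S100g was called lower among the low-depth mice alone in 3 of 3. This argues against a difference between batches for the low-depth mice only. At high depth the ages overlapped in each of these classes. The lowest young and highest old values there were 2.09 and 2.8 CPM (goblet-like), 3.81 and 4.89 CPM (stem-like) and 7.05 and 7.44 CPM (cycling-like). A fall in the low-depth mice alone stays open for these classes. At high depth a fall was called in 0 of the 2 that could be tested (-1.60 in the stem-like class with 2 young and 2 old mice, and -1.32 in the cycling-like). A biological difference with age, which may explain the fall, stays open as well.

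The list of 13 mitochondrially encoded genes was called higher in old mice in 3 classes by camera, in 0 with an estimated correlation and with 0 of its genes called, and this may come from the libraries of Young 5 alone. Without Young 5 the median log2 change of the list fell below 0.5 of its full value in 3 of the 3 classes in which it was called, from 0.44 to 0.11 in the colonocyte-like, 0.60 to 0.22 in the stem-like and 0.44 to 0.07 in the cycling-like class. These medians come from a limma fit to log2 CPM of the sums per mouse, and their full values differ from the medians given in the Results. In the stem-like class camera still called the list without Young 5, so Young 5 alone may not account for that call. Among the high-depth mice alone the median reached 0.5 of its full value in 0 of 3 classes (0.13, 0.26 and 0.11, against 0.84, 0.90 and 0.85 among the low-depth mice). A change in the low-depth mice alone cannot be told apart from Young 5, since Young 5 is 1 of the 2 young low-depth mice. A biological difference with age was not excluded.

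A small group of cells outside the comparisons, 89 cells in parts 0, 5 and 6 of cluster 37, carried genes of the small intestine such as Fabp6 and Defa24. Parts 1 to 3 shared leading genes with them (Ccl25 in parts 1 and 3, Fabp1 and Lyz1 in part 2). The listed genes were not tested there, so the group may be larger. Of the listed enterocyte genes 10 of 12 were over 10 times higher in parts 0 and 6 than in the other cells of the same libraries (Fabp6 16290 against 67.4 CPM). Fabp6, Apoa1, Apoa4, Sis and Rbp2 also led these parts, so their excess was largely fixed by the clustering. Among listed genes that did not lead, Enpep had 160 against 1.81 CPM, but Slc10a2 and Fabp2 were only 5.71 and 2.31 times higher. The argument against free RNA there thus rests on genes that did not lead. In part 5, 7 of 7 Paneth genes were 55.2 to 436 times higher (Defa24 204800 against 601 CPM, with a UMI in 96.4% of the other cells). Defa24, Defa30, Defa22 and Lyz1 led that part. Parts 0 and 6 (64 cells, 8 mice) came from cecum libraries in 71.9% of cells against 45.9% expected from the other cells of the same mice, so ileal tissue taken with the cecum is a candidate explanation, and the EpCAM sort would not remove it. Part 5 (25 cells, 3 mice) gave 16.0% against 21.2%, and with so few mice its origin cannot be told apart. Both shares were judged by a binomial interval over single cells, which takes no account of the spread between mice. No biological explanation was tested.

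In 4 genes of the goblet-like class the age difference differed between compartments: Ccz1 (adjusted p = 0.00119), Spink1 (0.0136), Kcnq1ot1 and Ly6e (0.0223 each). Of 100 regroupings of the mice 10 called as many genes as the real 4, with 62 the highest other, so chance is not excluded. What lies behind the highest value was not tested. In the colonocyte-like class the real count by edgeR was 0 (358 at an unadjusted p below 0.05, 3 by DESeq2), which all 100 of 100 regroupings reach by construction, so this says nothing about chance (highest other 123).

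A single mouse lay far from the others of its group in 7 of the 94 groups examined, where chance gives 4.7, about 1 in 20. The share of tuft-like cells in Young 4 was 1.31 points above the mean of its compartments, and that of T cell-like cells in Old 1 was 0.561 points above, from 1 cell. Log2 CPM of Cox6b2 in the colonocyte-like class was 3.71 in Young 4, and that of Meg3 in the goblet-like class 1.34 in Old 1. Kif26a had log2 CPM of -0.47 in Old 2 in the cycling-like and -1.36 in Young 2 in the goblet-like class. Ccnb1 had log2 CPM of 3.03 in Old 5 in the goblet-like class.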

How the results depend on the processing

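Naming the unnamed clusters, leaving out cluster 37, removing doublets from the compartment comparisons, and the age lists without single mice, with the replicate block or without the batch term were tests chosen after the results were seen. Of the 83 named genes, 0 reversed under any alternative; of 1006 values under other settings 853 stayed on their side of the threshold, 136 fell short of it and 17 passed it, and with single mice left out 817 of 905 stayed, 84 fell short and 4 passed. Of the shares, 0 reversed: 189 of 217 values under other settings and 248 of 308 with mice left out stayed on their side, 26 and 57 fell short, and 2 and 3 passed. The replicate block, which pairs mice by number, changed the calls named in the report beside their genes and the counts given here, and no other that could be fitted; Sprr1a in goblet-like and Kif26a in cycling-like cells could not be tested with it. Unless said otherwise, the cause was not tested. Depth differs between mice, so the high-depth mice alone are 3 young and 3 old (2 and 2 in the stem-like class) and the low-depth mice alone 2 young and 3 old.

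The age counts (17 colonocyte-like, 15 goblet-like, 8 stem-like, 10 cycling-like) depended on the batch term, without which they were 0, 0, 0 and 2 by edgeR. DESeq2 gave 32, 31, 26 and 23, and no gene filter 246, 224, 184 and 121. The replicate block gave 10 colonocyte-like and 37 stem-like genes. Without the compartment offset the counts were 11 colonocyte-like, 33 goblet-like and 2 cycling-like. Limma-voom gave 7 goblet-like and 18 stem-like genes. Cecum alone gave 6 colonocyte-like, 3 stem-like and 2 cycling-like, proximal colon alone 1 colonocyte-like, 5 goblet-like and 3 cycling-like, and distal colon alone 1, 6 and 2 in these classes, with fewer cells. High-depth mice alone gave 2 colonocyte-like, 0 goblet-like and 0 cycling-like, and low-depth mice alone 3, 24, 3 and 5 in the 4 classes, with fewer mice. In goblet-like cells a stricter filter gave 7, at least 50 cells 30 and at most 200 cells 6. In stem-like cells at least 10 cells gave 15 and naming the unnamed clusters 15. With single mice left out the counts ranged from 6 to 20, 5 to 32, 6 to 19 and 3 to 17.

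Between compartments, young mice alone gave, for proximal colon against cecum, 968 colonocyte-like, 1020 goblet-like and 336 stem-like genes. For distal against proximal colon they gave 823, 582 and 84, and for distal colon against cecum 1659 goblet-like and 171 stem-like; the stem-like ones rest on 1 distal library, Young 4, assumed to vary like the others. Old mice alone gave 2508 colonocyte-like genes for distal colon against cecum, 1190 colonocyte-like and 810 stem-like for proximal colon against cecum, and 844 and 255 for distal against proximal colon. These have fewer mice. Without the mouse as block the counts were 1487, 1811 and 479 for proximal colon against cecum, 1341 goblet-like and 141 stem-like for distal against proximal colon, and 508 stem-like for distal colon against cecum. Naming the unnamed clusters gave 5168, 2661 and 4306 stem-like genes for distal against cecum, proximal against cecum and distal against proximal, and at least 50 cells 2343 for proximal against cecum. With single mice left out the colonocyte-like count for distal against proximal colon ranged from 1296 to 2131, and the stem-like counts from 439 to 1214, 808 to 2245 and 158 to 513. The interaction count with no gene filter was 95 colonocyte-like and 118 goblet-like, 17 goblet-like with at least 50 cells and 3 colonocyte-like with DESeq2, and ranged from 0 to 6 and from 1 to 7 with mice left out.

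The called shares kept their sign in the alternatives run. The naming of the large unnamed distal clusters had little marker support, so it cannot show how their cells would change these shares. A higher minimum of cells leaves fewer pairs, which raises the smallest p the exact test can reach. With at least 200 cells per library the difference from cecum to distal colon was -26.97 points for colonocyte-like, 20.5 for goblet-like and -7.53 for cycling-like cells, from cecum to proximal colon -10.3 colonocyte-like and 15.1 stem-like, and from proximal to distal colon -16.7, 23.4, -28.6 and -7.44 for colonocyte-like, goblet-like, stem-like and cycling-like. None of these 9 passed. With the unnamed clusters named these were -21.2, 13.9 and -2.84, then -9.14 and 11.6, then -12.5, 22.1, -4.91 and -4.03, and again none of the 9 passed. Resolution 0.8 gave 15.1 for goblet-like cells from cecum to distal colon, -6.39 and 9.51 for colonocyte-like and stem-like from cecum to proximal, and -23.9 for colonocyte-like from proximal to distal. Resolution 2.5 gave -8.62 and 16.6 from cecum to proximal, and a cycling-like difference of -9.43 there that passed. Without the mouse as block the colonocyte-like difference from cecum to proximal was -10.4 and no longer passed, and the stem-like one from cecum to distal, -7.27, passed. At least 20 cells gave -5.35 for cycling-like from proximal to distal. With mice left out, differences from cecum to distal ranged from -26.96 to -21.1 (colonocyte-like), 10.1 to 16.8 (goblet-like), -9.11 to -6.12 (stem-like), -7.66 to -6.4 (cycling-like) and -0.972 to -0.575 (tuft-like). From cecum to proximal they ranged from -10.9 to -7.41 (colonocyte-like) and 15.1 to 19.5 (stem-like). From proximal to distal they ranged from -18.5 to -13.2 (colonocyte-like), 18.1 to 23.8 (goblet-like), -30.5 to -27.6 (stem-like), -8.34 to -6.86 (cycling-like) and -1.23 to -0.285 (tuft-like).

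Counts of gene lists depended on the assumed correlation. With an estimated one the age counts went from 8, 8, 11 and 9 to 0 in each class, and the compartment counts to 0 except 1 for colonocyte-like cells from proximal to distal colon. Fry gave 0, 0, 1 and 0 for age, 17 colonocyte-like for distal against cecum, 14 goblet-like for proximal against cecum and 12 goblet-like for distal against proximal. Without the batch term 4 goblet-like age lists were called. With mice left out the age counts ranged from 5 to 10 (colonocyte-like), 3 to 13 (goblet-like) and 5 to 12 (cycling-like). The use of all deposited cells and of a mitochondrial limit of 15% removed nothing, so they test nothing, and age in stem-like cells of the distal colon alone could not be fitted.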

Other observations

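The regroupings of the samples were set before the results were seen, and a test of chromosome X was chosen after, on the genes already called, so its p is not used.

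Chance is argued against for the age counts in each class taken alone, with no adjustment over the classes, which share the same mice. In the stem-like and cycling-like classes the highest other regrouping called more genes than the real one. Of 100 regroupings of the mice, the real one included, 1 called as many as the 17 genes of the colonocyte-like class (highest other 10), 1 as many as the 15 of the goblet-like class (13), 3 as many as the 8 of the stem-like class (142) and 2 as many as the 10 of the cycling-like class (26). The regrouping with 142 genes had 0 high-depth mice among its young. With the depth batch as a term, its contrast rests on low-depth mice alone, and what lies behind it was not tested. Within the high-depth and low-depth mice the real grouping of the stem-like class gave 8 (2 against 2 mice) and 3 genes. The regrouping with 26 genes was balanced for depth, and what lies behind it was not tested either. Among regroupings that part as many same-numbered pairs, 1 of 32 reached the real count in the colonocyte-like, goblet-like and cycling-like classes (highest others 1, 2 and 1) and 1 of 24 in the stem-like class (3). The other regroupings put same-numbered mice, which share a depth batch, on the same side.

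For the compartments chance is argued against too, in each comparison taken alone. Of 100 relabellings within mice, 1 reached the 4184 genes between distal colon and cecum in colonocyte-like cells (highest other 2523), 1 the 2551 between proximal colon and cecum (211) and 1 the 2078 between distal and proximal colon (57). In goblet-like cells 1 reached 3305 (179), 1 reached 2834 (1062) and 1 reached 2252 (671). In stem-like cells 2 reached 1009 (1150), 1 reached 1549 (101) and 2 reached 392 (440).

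Of the 14 genes that fell with age in some class, Bex1, Bex4, Mageh1 and S100g lie on chromosome X, Bex1 and Bex4 close together. This was noticed among the called genes, so how often chance gives it is left open.

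In colonocyte-like cells Apob and Vsig2 had the lowest adjusted p for a difference of the age effect between compartments, 0.0735 each. The unnamed clusters 15, 18 and 26 came from the distal colon in 97.3%, 97.3% and 90.7% of their cells, with Aqp4, Sycn, Nxpe2, Ggh and Hoxb13 among the leading genes of the unnamed clusters. Part 1 of cluster 37, led by Olfm4, Jaml and Gkn3, held 42 cells, 100% of them from young mice and 95.2% from Young 5. Parts 2 and 3 held 35 and 30 cells, 97.1% and 73.3% from young mice (82.9% from Young 5 and 40.0% from Young 4).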
